A study of Caenorhabditis elegans with 33 samples.

How the data were processed

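Messenger RNA was measured in whole L4 Caenorhabditis elegans of 5 genotypes with 3 libraries each, and small RNA in 18 libraries of 1 sample each. According to the labels, total RNA was depleted of ribosomal RNA and sequenced with strand information kept by dUTP. Small RNAs of 18 to 28 nt were gel-purified and treated with polyphosphatase or TAP, enzymes that open the 5' ends of triphosphorylated RNAs to ligation. Lysates were either kept as input or incubated with anti-HA or anti-GFP beads to give the immunoprecipitate. The labels name Trimmomatic, TopHat2, HTSeq, DESeq2 and Cuffdiff for the series, with no order, and no genome build or annotation, so no positions are given for any gene.

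The mRNA values were deposited by the authors as FPKM per gene and replicate, as estimated by Cuffdiff. The table holds 20517 genes, of which 20063 matched a RefSeq locus tag, 11412 of these carry a gene class symbol, and 2509 are at 0 in all 15 libraries. FPKM sums per library lay between 1182300 and 1299300, genes of at least 1 FPKM between 13070 and 13727, and genes at 0 between 4486 and 6385. The mean correlation of a library with the others of its genotype was 0.92 to 0.958 across genes. The read depth of these libraries is unknown, so no counting interval or detection floor is given for them. Some zeros sit in libraries of genes that are otherwise abundant: T05C12.15 is at 0 in 1 alg-1(gk214) library and has a median of 1731 FPKM over the 15. A gene whose libraries of 1 group are all at 0 is therefore given as listed at 0, with no fold.

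The small RNA values were deposited by the authors as RPM, reads scaled to the total of the library, in tables of miRNAs, 21U piRNAs, CSR-1 siRNAs and Mutator siRNAs. The siRNA tables share 27 genes, which were counted in each. Low values are whole multiples of 1 step per library, taken as 1 read. Within a tolerance of 0.02 of a read, 92.6% to 97.5% of miRNA values and 99.1% to 99.6% of piRNA values were whole. This gave total reads of 1622092, in wild type adult 2, to 24518714, in the GFP::ALG-5 input. Copies of 1 mature miRNA were summed, from 375 entries to 368 names. Wilson 95% intervals of shares are from these reads and cover counting error only, since the reads carry no molecular identifiers.

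Genes with a mean of at least 1 FPKM in at least 1 genotype were tested, 15174 in all, as log2 of FPKM plus 1, in limma 3.58.1 with a mean-variance trend and all 15 libraries in 1 model (10 residual degrees of freedom, 3.87 prior degrees of freedom). Each mutant was compared with wild type, both alg-5 alleles together with wild type, and 3 pairs of mutants with each other, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. DESeq2 and edgeR need counts and were not used on FPKM. On simulated data with the spread of these libraries, the test recovered 38 of 100 genes changed by 1 on the log2 scale and 69 of 100 changed by 2, with 6 false calls, and made 0 calls when nothing was changed. The simulated genes were independent and had the same spread in each genotype. The simulation therefore does not show how unequal spread or correlated genes affect the calls.

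The gene lists, drawn up before the data were examined along with the comparisons, the thresholds and the main alternatives, cover spermatogenesis, major sperm proteins, oogenesis and egg, germline sex determination, germline mitosis and meiosis, heterochronic genes, miRNA machinery, siRNA and piRNA machinery, vitellogenin and adult genes, cuticle and molting, collagens, muscle, neurons, intestine, somatic gonad, male tail neurons, embryo, stress and immunity, and replication-dependent histones. Of the 19 lists, 18 had at least 5 tested members and entered the list test. col-19 is in both the adult and the collagen list, and lin-41 in both the oogenesis and the heterochronic list. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry as an alternative. Camera compares a list with the other genes, whereas fry asks whether the list moves 1 way.

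Genes were named by a rule: per mutant, the 8 largest increases and 8 largest decreases among genes past the threshold with a mean of at least 5 FPKM in 1 group and groups that do not overlap, at most 2 per gene class and at most 2 with a sequence name only. Up to 4 members of each list with the largest change past the threshold were added, as were alg-1, alg-2 and alg-5 in every genotype, and lin-14, lin-28, lin-41, hbl-1, lin-29 and daf-12 whatever their result. In the comparison of both alleles and between mutants, only genes that the rule had taken against wild type and that passed there are named. For miRNAs, the 5 highest and 5 lowest of at least 10 RPM were taken.

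Class shares are shares of the sum of the 4 small RNA classes. Immunoprecipitates and inputs were compared by log2 ratio per construct with an exact sign-flip test over 5 constructs, for which 0.0625 is the smallest 2-sided p. miRNAs of at least 10 RPM on average were tested in limma on log2 of miRNA-scaled RPM plus 1, that is, RPM rescaled to the miRNA total of the library. The immunoprecipitate model (164 miRNAs) holds 1 pair of libraries per construct and 3 residual degrees of freedom. Its prior degrees of freedom came out infinite, so each p rests on a spread pooled over all miRNAs by abundance. The model of adult mutants (154 miRNAs) compares 1 library per mutant with the 3 wild type adults, with 2 residual and 3.45 prior degrees of freedom, and assumes that a mutant would vary as wild type does. On simulated data the first model recovered 8 of 20 miRNAs changed by 3 and 18 of 20 changed by 6, and the second 5 of 20 changed by 2 and 11 of 20 changed by 4, with 0 and 1 false calls. The simulated miRNAs were again independent, with the same spread in each library. miRNA families were let-7, lin-4, mir-35, mir-51, mir-58 (without mir-58b), mir-44 (with mir-61), mir-2 (with mir-250), mir-64 and mirtrons. Both arms of a hairpin count as members of its family.

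The alternatives were another pseudocount, filter and scaling, a model of the compared groups only, a replicate block, leaving out each library, an estimated correlation or fry for lists, DESeq2 1.42.0 on recovered reads, another denominator, and leaving out the ALG-1::HA::ALG-2 construct. Library weights, edgeR 4.0.16 on recovered reads, the deposited RPM, also for L4 alg-5(ram2), and the model of the compared groups only for direct comparisons were added after the data had been seen. The replicate numbers were checked for pairing: after genotype means were removed, correlations between libraries of equal number lay between -0.0255 and 0.0904 over 10 pairs of genotypes, so the numbers were not taken as pairs. The alg-5 level is not lowered in alg-5(tm1163), so FPKM does not check that label. No deposited column was left out. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.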

Results

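The series measured long RNA and small RNA in Caenorhabditis elegans with mutations in, or tagged forms of, ALG-1, ALG-2 or ALG-5, Argonaute proteins that bind small RNAs. Messenger RNA was measured in L4 larvae of 5 genotypes with 3 libraries each: wild type, alg-5(tm1163), alg-5(ram2), alg-1(gk214) and alg-2(ok304). The larvae were collected 49 h after the L1 stage, except alg-1(gk214), which was collected at 53 h to match the stage. Small RNA was measured in 18 single libraries with 1622092 to 24518714 total reads each. These are 3 wild type adults, 1 adult each of alg-1(gk214), alg-2(ok304) and alg-5(tm1163), wild type and alg-5(ram2) L4 larvae, and an input and an immunoprecipitate for each of 5 tagged constructs. HA::ALG-1, HA::ALG-2, ALG-1::HA::ALG-2 and HA::ALG-5 were taken from adults at 68 h and GFP::ALG-5 from L4 larvae at 49 h. Values of mRNA are mean FPKM ± SD with n = 3, log2 changes are those fitted by limma with their SE, and each adjusted p is from limma. The depth of the mRNA libraries is unknown.

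**Figure D1:**
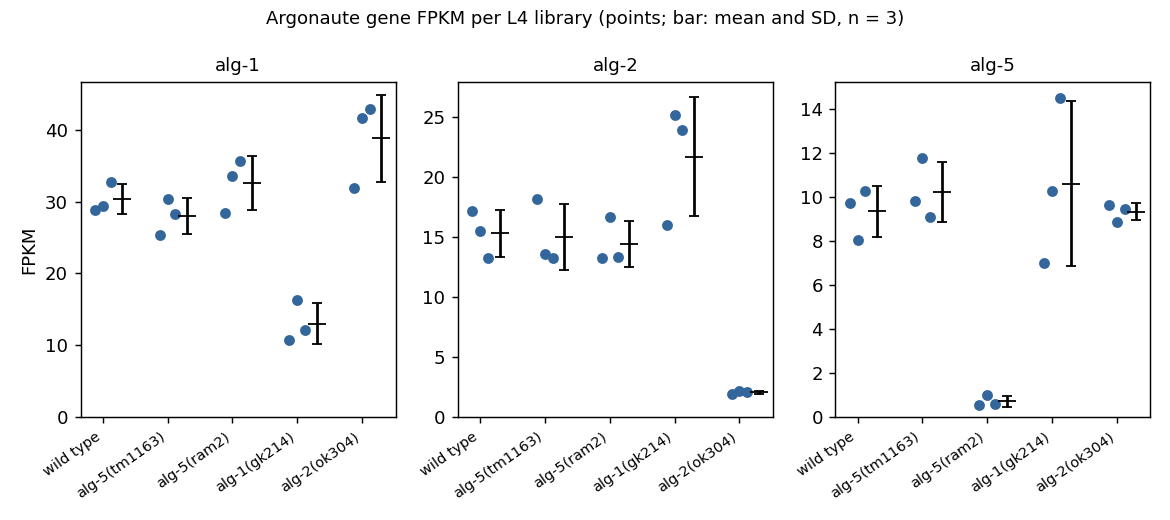
FPKM of alg-1, alg-2 and alg-5 in each L4 mRNA library (points), with the mean and SD of each genotype (n = 3). alg-5 was 0.720 ± 0.241 FPKM in alg-5(ram2) and 10.2 ± 1.37 FPKM in alg-5(tm1163), against 9.35 ± 1.17 FPKM in wild type.

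alg-5(tm1163) larvae were compared with wild type to ask which transcripts depend on alg-5 at the L4 stage. The gene nep-22 (T25B6.2), of the neprilysin family of peptidases, fell from 193 ± 7.69 to 61.4 ± 4.52 FPKM (log2 -1.64, SE 0.0829, adjusted p = 2.27e-07, n = 3). The DNA end-joining factor nhj-1 (H19N07.3) fell from 78.0 ± 11.5 to 13.2 ± 5.02 FPKM (log2 -2.53, SE 0.223, adjusted p = 0.00016, n = 3). The peptide gene nlp-119 (K02A6.4) was listed at 0 in every wild type library and at 5.56, 11.5 and 5.98 FPKM in the mutant. The histone gene his-32 (F17E9.10) rose by 2.45 on the log2 scale, from 23.8 ± 14.4 to 116 ± 25.7 FPKM (adjusted p = 0.0291). The tRNA methyltransferase family gene trmt-10A (F25H8.1) rose by 1.01, from 13.98 ± 0.832 to 29.2 ± 1.25 FPKM (adjusted p = 0.016). Genes of the major sperm protein, the cytoskeletal protein by which nematode sperm crawl, fell as a list (camera adjusted p = 1.21e-22, and adjusted p = 0.0564 with an estimated correlation). Of its 29 tested members 28 had a lower mean, with a median log2 change of -1.03. Of these, 3 fell over all genes and 20 adjusted over the list alone, among them msp-81 (K07F5.1), from 604 ± 86.2 to 247 ± 30.0 FPKM. msp-10 and msp-152 fell by 1.75 and 1.32, and the nematode-specific peptide gene nspd-2 (K07F5.5) by 0.79. The spermatogenesis list (44 members, median -0.36) fell by camera (adjusted p = 0.00124, and adjusted p = 0.4545 with an estimated correlation), as did cuticle and molting genes (35 members, median -0.28, adjusted p = 5.2e-05, and adjusted p = 0.493 with an estimated correlation). The oogenesis and egg list (34 members, median -0.16) fell as well (adjusted p = 0.022, and adjusted p = 0.4545 with an estimated correlation). limma called 0 members of these 3 lists over all genes, where 8, 14 and 3 had an unadjusted p under 0.05. Adjusted over the list alone, 3 spermatogenesis and 7 cuticle genes fell, 1 cuticle gene rose, and 0 oogenesis genes were called. Collagens moved both ways: limma called 0 of 117 over all genes, with 42 at an unadjusted p under 0.05, and 7 rose and 2 fell adjusted over the list alone. Of 46 histone genes 1 rose, 3 adjusted over the list alone; their median was -0.09 and their mean 0.24, and the list was not called. The timing genes did not pass: lin-14 differed by 0.48 (adjusted p = 0.362) and lin-28, lin-41, hbl-1, lin-29 and daf-12 by -0.20 to 0.20. alg-5 itself (T23D8.7) differed by 0.12 (SE 0.257, adjusted p = 0.912).

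In all, limma called 5 genes higher and 8 lower in alg-5(tm1163), with 1633 at an unadjusted p under 0.05. The groups did not overlap for 12.6% of genes, where chance gives 10%. The count was 7 without wild type replicate 1, 32 without wild type replicate 3, and 5, 7 and 6 without replicates 1, 2 and 3 of the mutant. nep-22, nhj-1 and nlp-119 kept their calls without each library. With only the compared groups in the model, 1 gene passed, nep-22 (adjusted p = 0.0179), and nhj-1, nlp-119 and the other genes named did not (0.119, 0.257 and up to 0.445). his-32 lost its call without each mutant replicate (adjusted p up to 0.12), and trmt-10A without those or wild type replicate 1 (up to 0.0801). msp-81 lost its call without wild type replicate 1 or 2 or mutant replicate 1 (up to 0.0898), nspd-2 without these or mutant replicate 2 (up to 0.115). msp-10 lost its call when any 1 library except mutant replicate 2 was left out (up to 0.185), and msp-152 when any except mutant replicate 3 was (up to 0.151). The other named genes were F40F12.9, higher by 2.80, F58A4.6, higher by 1.98, and C54G4.3, with a log2 change of -2.45. The first and second lost their calls when any 1 library except wild type replicate 3 was left out (adjusted p up to 0.174 and 0.146), and C54G4.3 without wild type replicate 1 or mutant replicate 1 or 3 (up to 0.126).

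The ram2 allele addresses the same question with a second mutation, and the transcript of the gene itself fell: alg-5 went from 9.35 ± 1.17 to 0.720 ± 0.241 FPKM (log2 -2.59, SE 0.257, adjusted p = 0.000702, n = 3). kreg-1 (F53A9.2) fell from 645 ± 197 to 114 ± 26.6 FPKM (log2 -2.47, SE 0.304, adjusted p = 0.00232). The bZIP transcription factor zip-10 (T27F2.4) fell from 159 ± 52.9 to 28.9 ± 0.389 FPKM, the serpentine receptor srr-6 (C13D9.1) from 24.4 ± 3.79 to 2.01 ± 1.44 FPKM, and the acyltransferase oac-6 (C31A11.5) from 47.1 ± 18.6 to 6.07 ± 1.14 FPKM. F13A7.11 fell by 2.64. Among genes that rose, his-31 (F17E9.12) went from 1.96 ± 2.72 to 22.4 ± 5.67 FPKM, his-32 from 23.8 ± 14.4 to 85.4 ± 9.72 FPKM and trmt-10A from 13.98 ± 0.832 to 29.7 ± 2.68 FPKM. The major sperm protein list fell by camera (median -0.41, lower in 26 of 29 members, adjusted p = 5.03e-05, and adjusted p = 0.665 with an estimated correlation). Muscle genes rose as a list (median 0.08, higher in 15 of 15 members, adjusted p = 0.00397, and adjusted p = 0.665 with an estimated correlation). limma called 0 members of either list over all genes, where 4 and 3 had an unadjusted p under 0.05, and 0 and 2 adjusted over the list alone. Of 46 histone genes 2 rose over all genes and 3 adjusted over the list alone. lin-14, lin-28, lin-41, daf-12, hbl-1 and lin-29 differed by -0.17 to 0.29 and did not pass.

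limma called 5 genes higher and 39 lower in alg-5(ram2), with 1165 at an unadjusted p under 0.05, and 12.3% of genes with groups that did not overlap, against 10% by chance. The count was 73 without wild type replicate 3, and 18, 27 and 23 without replicates 1, 2 and 3 of the mutant. alg-5, kreg-1, srr-6, oac-6, F13A7.11, F58A4.6 (higher by 2.29) and trmt-10A kept their calls without each library. zip-10 lost its call without mutant replicate 1 (adjusted p up to 0.0574), his-32 without each mutant replicate (up to 0.197), and his-31 without those or wild type replicate 1 (up to 0.112). The BTB and MATH domain gene bath-25 (log2 -2.35) lost its call without wild type replicate 1 or 3 or mutant replicate 2 or 3 (up to 0.13), and K02B12.6 (log2 -2.71) when any 1 library except wild type replicate 3 was left out (up to 0.211). With only the compared groups in the model the count was 16, and trmt-10A, his-31, his-32, bath-25 and K02B12.6 lost their calls (adjusted p up to 0.352), while alg-5, kreg-1, zip-10, srr-6, oac-6, F13A7.11 and F58A4.6 kept theirs.

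Both alleles were set together against wild type, and directly against each other, to see what they share. trmt-10A rose by 1.02 over both alleles (adjusted p = 0.00675), his-32 by 2.24 (adjusted p = 0.0137) and F58A4.6 by 2.14 (adjusted p = 0.00798), while nep-22 and kreg-1 fell by 0.86 and 1.68 (adjusted p = 0.000174 and 0.0171). This contrast averages the alleles, so 1 allele alone can carry it. nep-22 differed by -0.07 in alg-5(ram2) (adjusted p = 0.911) and kreg-1 by -0.89 in alg-5(tm1163) (adjusted p = 0.309), neither called. The alleles differed at nep-22, which was 184 ± 6.43 FPKM in alg-5(ram2) and 61.4 ± 4.52 FPKM in alg-5(tm1163) (log2 1.57, adjusted p = 4.13e-07). They also differed at nhj-1, 53.5 ± 9.31 against 13.2 ± 5.02 FPKM (log2 1.99, adjusted p = 0.00153), and at alg-5 (log2 -2.71, adjusted p = 0.000404). nlp-119 was listed at 0 in each alg-5(ram2) library. As a list, the major sperm protein genes fell over both alleles by camera (median -0.72, 1 gene lower over all genes, 17 lower and 1 higher adjusted over the list alone, adjusted p = 5.45e-16, and adjusted p = 0.161 with an estimated correlation). Between the alleles the same list was higher in alg-5(ram2) (median 0.69, adjusted p = 2.01e-15, and adjusted p = 0.0888 with an estimated correlation), as were cuticle (0.36, adjusted p = 2.42e-11, and adjusted p = 0.132 with an estimated correlation), oogenesis (0.28, adjusted p = 1.04e-06, and adjusted p = 0.0766 with an estimated correlation) and spermatogenesis genes (0.38, adjusted p = 6.15e-05, and adjusted p = 0.189 with an estimated correlation). limma called 0 members of these 4 lists between the alleles over all genes, where 14, 10, 8 and 4 had an unadjusted p under 0.05, and 9 major sperm protein genes and 0 of the others passed adjusted over the list alone.

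Over both alleles limma called 6 genes higher and 19 lower, with 1586 at an unadjusted p under 0.05. The count was 7, 12 and 130 without wild type replicates 1, 2 and 3. trmt-10A, his-32, nep-22 and nhj-1 kept their calls without each library, F58A4.6 lost its call without wild type replicate 1 (adjusted p up to 0.0506), and kreg-1 without wild type replicate 1 or 2 or alg-5(tm1163) replicate 3 (up to 0.105). With only the compared groups in the model his-32 lost its call over both alleles (adjusted p = 0.0821) and nhj-1 its call between the alleles (adjusted p = 0.0722), where 5 genes passed. Between the alleles 5 genes were higher and 7 lower in alg-5(ram2), with 870 at an unadjusted p under 0.05, and the count was 4 without alg-5(tm1163) replicate 3, 7 without its replicate 2, 4 and 5 without alg-5(ram2) replicates 2 and 3, and 8 without replicate 1 of either. Across genes the log2 changes of the alleles correlated at r = 0.61, to which the shared wild type libraries add (0.507 in simulated unchanged groups), and genes are not independent replicates. The simulation gives each group the same spread. Wild type libraries correlated less with their own genotype (0.920 to 0.931) than alg-5(ram2) libraries did (0.954 to 0.958). The simulated value may thus be too low. Of the genes called, 3 were higher and 1 lower in both alleles.

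In alg-1(gk214), collected at 53 h against 49 h, transcripts of cuticle, yolk, sperm and developmental timing genes differed from wild type. The adult cuticle collagen col-19 (ZK1193.1) rose from 1.26 ± 1.83 to 50.8 ± 8.51 FPKM and col-119 (C53B4.5) by 5.91 on the log2 scale (SE 0.397, adjusted p = 9.02e-07). The collagens bli-1 (C09G5.6) and bli-2 (F59E12.12), which build the struts of the adult cuticle, fell from 490.3 to 15.8 FPKM (SE of the log2 change 0.324, adjusted p = 6.45e-07) and from 849 to 43.9 FPKM. kreg-1 fell from 645 ± 197 to 17.3 ± 7.57 FPKM. Of 117 collagens 64 rose and 23 fell over all genes, and 65 and 25 adjusted over the list alone (median 1.08, camera adjusted p = 2.84e-11). Of 35 cuticle and molting genes 31 fell (32 adjusted over the list alone, where 1 rose), among them the hedgehog-like wrt-1, by 2.17 (camera adjusted p = 1.23e-28). Both calls held with an estimated correlation, as did that of the histones, of which 10 of 46 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.000805). The yolk protein gene vit-5 (C04F6.1) rose from 0.0328 to 15.4 ± 1.55 FPKM, and 6 of 8 genes of the vitellogenin and adult list rose, also adjusted over the list alone (median 1.93, camera adjusted p = 8.32e-07, and adjusted p = 0.0746 with an estimated correlation). The eggshell gene perm-2 rose by 2.00 and the Nanos-related nos-2 by 2.39. In the oogenesis and egg list 6 genes rose, also adjusted over the list alone (median 0.46, camera adjusted p = 0.000122, and adjusted p = 0.0606 with an estimated correlation). The uterine lumen gene ule-5 and F14F8.8 were listed at 0 in each wild type library, and at 27.1 to 47.2 and 65.1 to 166 FPKM in the mutant.

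Of the genes that time larval development, lin-14 (T25C12.1) rose from 15.9 ± 3.67 to 33.5 ± 0.651 FPKM (log2 1.06, SE 0.183, adjusted p = 0.00144) in alg-1(gk214). The RNA-binding lin-41 (C12C8.3) rose from 6.75 ± 1.13 to 14.5 ± 0.909 FPKM and the nuclear receptor daf-12 (F11A1.3) from 13.5 ± 1.94 to 26.2 ± 4.22 FPKM. lin-29 (W03C9.4), the zinc finger factor of the switch from larva to adult, fell from 28.7 ± 1.15 to 14.9 ± 3.22 FPKM, and its cofactor mab-10 by 1.65. The nuclear receptor nhr-25 rose by 1.78. lin-28 differed by -0.24 and hbl-1 by 0.36, neither called. Of 18 heterochronic genes 6 rose and 3 fell, 8 and 4 adjusted over the list alone. Of 29 major sperm protein genes 22 fell (25 adjusted over the list alone), such as msp-3, by 1.78 (camera adjusted p = 1.98e-13, and adjusted p = 0.0606 with an estimated correlation). Of 44 spermatogenesis genes 8 fell, also adjusted over the list alone, such as the sperm-supplied spe-11, by 1.36 (median -0.68, camera adjusted p = 4.17e-05, and adjusted p = 0.0913 with an estimated correlation). In the intestine list 7 of 13 fell (8 adjusted over the list alone), with the proteases cpr-1 from 946 to 486 and cpr-6 from 702 to 327 FPKM (median -0.50, camera adjusted p = 5.46e-05, and adjusted p = 0.0606 with an estimated correlation). Stress and immunity genes went both ways, 4 of 18 up and 4 down, also adjusted over the list alone: the infection response gene irg-5 fell by 1.53 and the small heat shock gene hsp-16.2 rose by 1.64. In the list of siRNA and piRNA machinery 3 of 40 rose and 2 fell, the same numbers adjusted over the list alone. In that of sex determination 2 of 21 rose (1 adjusted over the list alone), with fog-1 up by 1.06. alg-1 (F48F7.1) fell from 30.3 ± 2.05 to 13.02 ± 2.88 FPKM (log2 -1.18, SE 0.172, adjusted p = 0.000375) and was the 1 of 14 miRNA machinery genes to pass. The innexin inx-9, at 2.99 against 9.64 FPKM, fell and was the 1 of 9 somatic gonad genes to pass. alg-2 was 21.7 ± 4.94 against 15.3 ± 1.96 FPKM (adjusted p = 0.18). limma called 0 of 34 germline mitosis and meiosis genes, with 1 at an unadjusted p under 0.05, and 0 of the muscle, neuron, embryo and male tail neuron genes, with 0 at that level.

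In alg-1(gk214) limma called 969 genes higher and 1276 lower, of which 612 and 807 by more than 2-fold, with 4261 at an unadjusted p under 0.05. The groups did not overlap for 27.6% of genes, against 10% by chance. mab-10 lost its call without wild type replicate 1 or mutant replicate 1 (adjusted p up to 0.0634). With only the compared groups in the model the count was 1117, and lin-41, daf-12, mab-10, fog-1 and inx-9 lost their calls (0.0547, 0.0514, 0.0703, 0.0710 and 0.0672). Collection hour and genotype go together in these libraries.

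**Figure D2:**
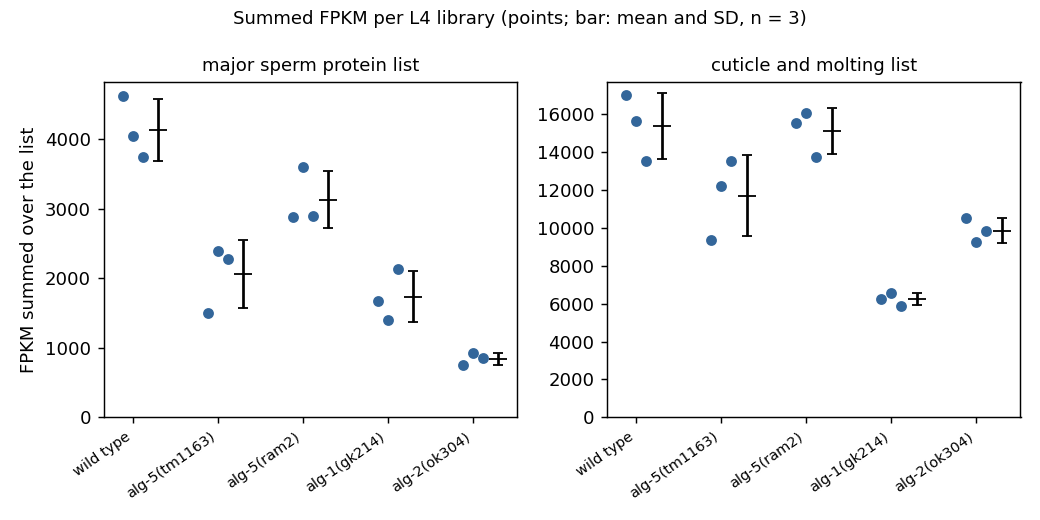
FPKM summed over the major sperm protein list (left) and the cuticle and molting list (right) in each L4 library (points), with the mean and SD of each genotype (n = 3). The major sperm protein sum was 3743 to 4624 in wild type and 747 to 923 in alg-2(ok304), and the cuticle sum 13548 to 16994 in wild type and 5892 to 6542 in alg-1(gk214).

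In alg-2(ok304), collected at the same hour as wild type, sperm, cuticle, collagen and yolk genes differed from wild type. Genes of the major sperm protein fell in 26 of 29 cases over all genes and 27 adjusted over the list alone (median -2.18, camera adjusted p = 6.39e-29). msp-81 fell from 604 ± 86.2 to 83.9 ± 15.3 FPKM (log2 -2.84, SE 0.178, adjusted p = 5.66e-07, n = 3). Of 44 spermatogenesis genes 20 fell (26 adjusted over the list alone, camera adjusted p = 1.48e-13), among them smz-1, by 1.83. bli-1 and bli-2 fell to 31.4 and 52.0 FPKM, and 28 of 35 cuticle and molting genes fell while 2 rose, the numbers being equal adjusted over the list alone (median -1.17, camera adjusted p = 2.41e-20). Of 117 collagens 65 rose and 16 fell (69 and 21 adjusted over the list alone, median 1.42, camera adjusted p = 4.96e-19), with col-19 up by 4.14. These 4 calls held with an estimated correlation. The vitellogenin and adult list rose, with vit-5 up by 2.99 and 4 of 8 genes called (5 up and 1 down adjusted over the list alone, median 1.23, camera adjusted p = 0.000447, and adjusted p = 0.211 with an estimated correlation). Muscle genes rose: the myosin heavy chain unc-54 (F11C3.3) went from 718 ± 55.6 to 1072 ± 75.7 FPKM (log2 0.58, SE 0.106, adjusted p = 0.00245), and 4 of 15 rose over all genes and 7 adjusted over the list alone (median 0.35, camera adjusted p = 3.14e-05, and adjusted p = 0.107 with an estimated correlation). Neuron genes were higher in 16 of 16 cases, 1 of them called, also adjusted over the list alone (median 0.27, camera adjusted p = 0.00968, and adjusted p = 0.0938 with an estimated correlation). The nuclear anchoring gene anc-1 (ZK973.6) was listed at 0 in each alg-2(ok304) library and at 20.2 to 22.4 FPKM in wild type. Heterochronic genes went up in 6 and down in 1 of 18 cases (7 and 4 adjusted over the list alone), with nhr-25 among those up. lin-14 was 26.1 ± 3.36 FPKM (log2 0.70, adjusted p = 0.0216) and lin-41 13.7 ± 2.07 FPKM (log2 0.93, adjusted p = 0.0227). daf-12 (0.60, adjusted p = 0.0546) and lin-29 (-0.55, adjusted p = 0.0801) did not pass, nor did lin-28 (-0.20) and hbl-1 (0.30). alg-2 (T07D3.7) fell from 15.3 ± 1.96 to 2.06 ± 0.114 FPKM (log2 -2.41, SE 0.215, adjusted p = 7.16e-06).

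In alg-2(ok304) limma called 739 genes higher and 1075 lower, of which 499 and 796 by more than 2-fold, with 3746 at an unadjusted p under 0.05 and 27.5% of genes with groups that did not overlap, against 10% by chance. lin-14 lost its call without wild type replicate 1 or mutant replicate 1 or 2 (adjusted p up to 0.0917), and lin-41 without wild type replicate 3 or mutant replicate 1 (up to 0.0971). lin-29 passed without mutant replicate 2 (adjusted p = 0.0266, and 0.0266 to 0.248 over the left-out libraries). With only the compared groups in the model the count was 1169, and lin-14 and lin-41 lost their calls (0.114 and 0.0646).

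The mutants of the related Argonautes alg-1 and alg-2 were compared directly, with the wild type libraries outside the contrast but in the model that sets the spread. alg-1(gk214) was collected at 53 h and alg-2(ok304) at 49 h, so hour and genotype cannot be told apart here. Genes of the major sperm protein were higher in alg-1(gk214) than in alg-2(ok304) (median 0.98, 8 genes over all genes and 19 adjusted over the list alone), with msp-81 at 223 ± 44.4 against 83.9 ± 15.3 FPKM (log2 1.40, SE 0.178, adjusted p = 0.000922). Oogenesis genes were higher as well (median 0.47, 4 genes, 10 adjusted over the list alone, camera adjusted p = 1.07e-09). Collagens were lower (median -0.22, 10 down, and 20 down and 3 up adjusted over the list alone, camera adjusted p = 3.23e-05), as were muscle genes in 15 of 15 cases (median -0.33, 1 gene, 10 adjusted over the list alone, camera adjusted p = 2.9e-09). These 4 of 13 camera calls held with an estimated correlation. irg-5 was 34.5 ± 5.60 FPKM in alg-1(gk214) and 108 ± 15.9 FPKM in alg-2(ok304) (log2 -1.62, adjusted p = 0.00189), and hsp-16.2 was 57.3 ± 8.81 against 12.22 ± 7.17 FPKM (log2 2.29, adjusted p = 0.0079). In all 99 genes were higher and 142 lower in alg-1(gk214), with 2164 at an unadjusted p under 0.05. The count was 159 without alg-1(gk214) replicate 1, 116 without its replicate 3, 128, 130 and 107 without replicates 1, 2 and 3 of alg-2(ok304), and 154 with only the compared groups in the model. Across genes the log2 changes of alg-1(gk214) and alg-2(ok304) against wild type correlated at r = 0.755 (0.507 in simulated unchanged groups). Both mutants had 524 genes higher and 668 lower, and 5 genes went opposite ways. Of the 39 genes lower in alg-5(ram2), 34 were also lower in alg-1(gk214) and 27 in alg-2(ok304), while across genes the changes of alg-5(ram2) correlated with theirs at r = 0.419 and 0.403, under the simulated 0.507. The covariance was above the simulated one, at 0.180 and 0.169 against 0.111, so r alone does not show less in common than the shared libraries give. The simulated values may be too low, as each group got the same spread, so the covariance does not show changes in common either. These overlaps use the same wild type libraries, and no expectation that allows for this was computed.

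alg-1(gk214) was also set against alg-5(tm1163), to ask how these 2 mutants differ. The alg-5 transcript is not lower in alg-5(tm1163). The first was collected at 53 h and the second at 49 h, so hour and genotype go together here as well. bli-1 was 15.8 ± 8.89 FPKM in alg-1(gk214) and 339.7 FPKM in alg-5(tm1163) (log2 -4.43, adjusted p = 2.14e-06), and nep-22 was higher by 1.56 in alg-1(gk214) (adjusted p = 2.2e-07). lin-41 was higher by 1.21 (adjusted p = 0.00558, and 0.0559 with only the compared groups in the model, where 904 genes passed). Cuticle genes were lower in 28 of 35 cases, also adjusted over the list alone (median -1.07, camera adjusted p = 1.94e-27), and collagens higher in 53 cases and lower in 13 (63 and 18 adjusted over the list alone, camera adjusted p = 8.74e-14). Oogenesis genes were higher in 7 cases (15 adjusted over the list alone, camera adjusted p = 1.75e-09), vitellogenin and adult genes in 6 of 8 (7 adjusted over the list alone) and histones in 10 of 46 (12 up and 2 down adjusted over the list alone). These 5 of 8 camera calls held with an estimated correlation. limma called 608 genes higher and 796 lower in alg-1(gk214), with 3431 at an unadjusted p under 0.05.

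Each Argonaute was precipitated by its tag to ask which small RNAs it holds. The miRNA share of the 4 small RNA classes was higher in the immunoprecipitate than in the input for 5 of 5 constructs, by a mean log2 ratio of 1.54 (SD 0.50). It went from 21.4% to 67.2% with HA::ALG-1, from 21.3% to 82.5% with HA::ALG-2, from 18.1% to 74.9% with ALG-1::HA::ALG-2, from 25.5% to 48.0% with HA::ALG-5 and from 42.7% to 93.0% with GFP::ALG-5. The 21U piRNAs, which guide silencing in the germline, were lower in 5 of 5 (mean -2.18, SD 1.09), as were siRNAs of the CSR-1 (-2.10, SD 1.16) and Mutator pathways (-1.72, SD 1.19). The 2-sided exact sign-flip p was 0.0625 for each class, also adjusted, the smallest that 5 constructs can give, so these shifts cannot pass 0.05. Each construct has 1 library per fraction. The Wilson 95% interval of the share with HA::ALG-5 was 47.9% to 48.1%, the widest of the 5 immunoprecipitates. When Mutator siRNAs were left out of the total, the mean log2 ratio was 0.73.

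**Figure D3:**
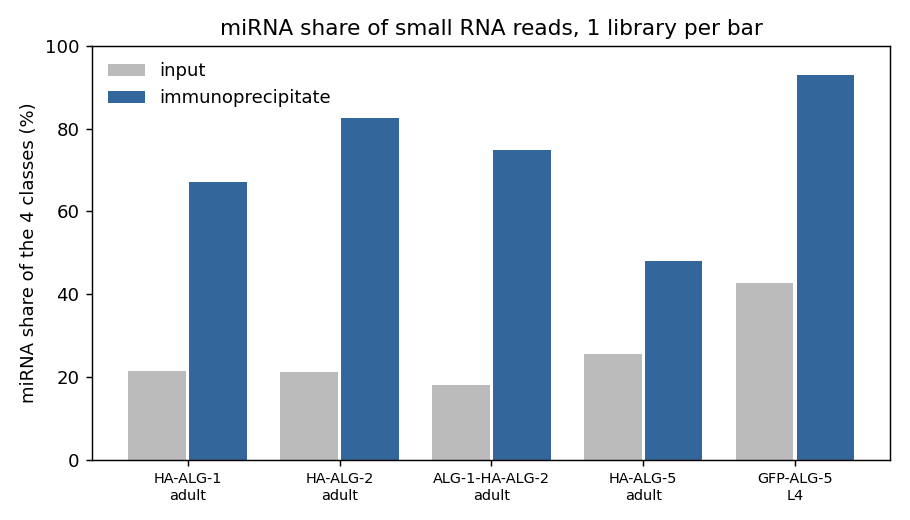
Share of miRNAs in the reads of the 4 small RNA classes, in percent, for the input (grey) and immunoprecipitate (blue) of each construct, 1 library per bar. The share was higher in the immunoprecipitate for 5 of 5 constructs and reached 93.0% with GFP::ALG-5.

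ALG-5 held a few miRNAs at high levels. miR-61-3p, miR-250-3p and miR-51-5p made up 34.3%, 28.6% and 23.5% of the miRNA reads in the GFP::ALG-5 immunoprecipitate, together 86.4%, against 0.63%, 0.546% and 0.963% in its input. With HA::ALG-5 they made up 12.8%, 24.9% and 8.31%, together 45.98%, against 0.558%, 0.503% and 0.458%. The HA::ALG-1 immunoprecipitate held most of miR-80-3p (12.8%) and miR-58-3p (11.6%), that of ALG-1::HA::ALG-2 most of miR-58-3p (10.96%) and miR-80-3p (10.04%), and that of HA::ALG-2 most of miR-35-3p (12.7%) and miR-36-3p (12.25%). The difference in enrichment between the 2 ALG-5 and the 3 other constructs was tested in limma: 11 of 164 miRNAs were more enriched by ALG-5 and 0 less, with 23 at an unadjusted p under 0.05. These are relative to the miRNA total: with the deposited RPM limma called 11 more and 10 less enriched. miR-250-3p differed by 8.31 on the log2 scale (SE 1.42, adjusted p = 4.89e-07), with ratios of 5.63 for HA::ALG-5 and 5.71 for GFP::ALG-5. miR-61-3p differed by 6.55 (SE 1.42, adjusted p = 0.000132) and miR-51-5p by 4.76 (SE 1.41, adjusted p = 0.0123). The highest was miR-58b-3p, at 10.58 (SE 1.33, adjusted p = 2.02e-12), followed by miR-36-5p at 8.44. miR-1829c, miR-250-5p, miR-72-3p, miR-4812-3p, miR-1829b and miR-51-3p differed by 5.70 to 7.13. Of the 11, miR-58b-3p, miR-1829c and miR-4812-3p were rare, under 10 RPM summed over the wild type and alg-5(ram2) L4 libraries. How far their log2 values depend on the pseudocount was not tested. The lowest values, not called, were -3.33 for miR-65-3p, -3.29 for miR-43-3p, -3.04 for miR-239b-5p and -2.89 for both miR-251 and miR-56-3p. DESeq2 called 28 more and 4 less enriched (46 at an unadjusted p under 0.05), and edgeR 5 and 0 (29), of which 3 were among the 11: miR-58b-3p, miR-1829c and miR-72-3p. miR-250-3p, miR-61-3p, miR-36-5p and miR-51-5p lost their calls with edgeR, with an adjusted p over the alternatives of up to 0.106, 0.125, 0.0714 and 0.3715. miR-61-3p, miR-51-5p, miR-51-3p, miR-250-5p and miR-1829b also lost theirs with no filter, and miR-51-5p when scaled to the 4 classes. The count was 7 without the ALG-1::HA::ALG-2 construct, where miR-72-3p, miR-1829b, miR-51-3p and miR-51-5p lost their calls. miR-250-5p, miR-1829b and miR-51-5p lost theirs without HA::ALG-1, and miR-51-3p without GFP::ALG-5. The spread behind each p is pooled over all miRNAs by abundance, and the ALG-5 constructs differ in tag and stage. The 3 other constructs come from 1 experiment and the ALG-5 constructs from others, so Argonaute and experiment cannot be told apart here.

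**Figure D4:**
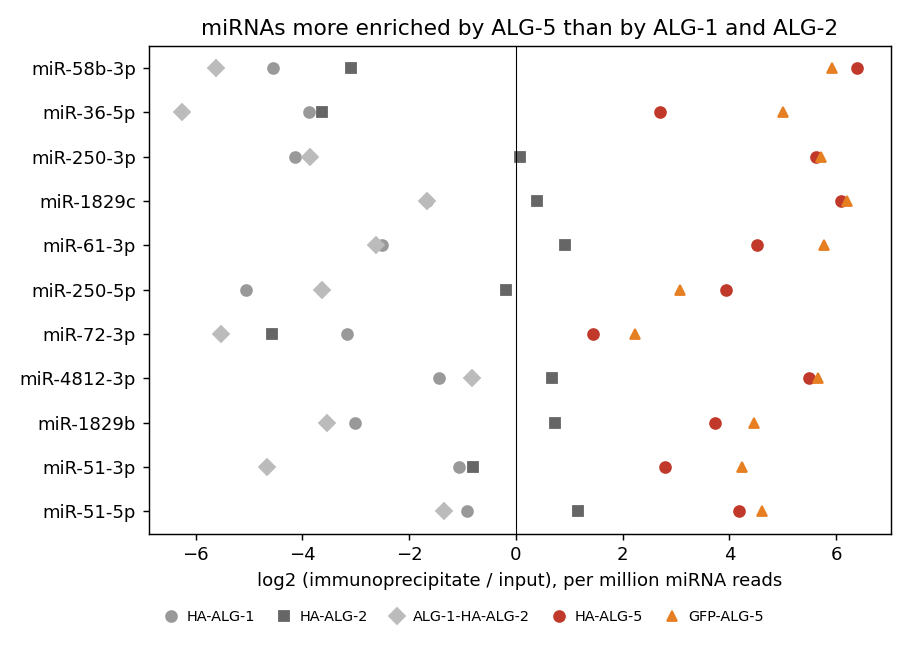
log2 ratio of immunoprecipitate to input, each scaled to the miRNA total, for the 11 miRNAs more enriched by ALG-5 (vertical axis) and the 5 constructs (symbols, 1 pair of libraries each). For miR-250-3p the ratio was 5.63 with HA::ALG-5, 5.71 with GFP::ALG-5 and 0.08 with HA::ALG-2.

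By family, reads of the mir-44 family summed were enriched by a log2 ratio of 3.28 with HA::ALG-5 and 4.38 with GFP::ALG-5, and those of the mir-2 family by 2.85 and 2.59. These sums are mostly single members, miR-61-3p and miR-250-3p. In the limma test of enrichment by ALG-5 over input, 1 of 7 mir-44 members rose and 3 fell (median -2.25), and 2 of 5 mir-2 members rose and 3 fell (median -2.54). The directions of that test depend on the tool: over all 164 miRNAs limma called 11 up and 71 down, DESeq2 19 and 3, and edgeR 0 and 0, with 21 at an unadjusted p under 0.05. Summed reads of the let-7 family, which promotes late larval fates, were depleted in both (-2.02 and -3.80), as were the lin-4 (-1.43 and -3.83), mir-58 (-1.15 and -3.82) and mir-64 families (-0.66 and -3.60) and the mirtrons (-1.12 and -3.27), all relative to the miRNA total. The summed mir-51 family had ratios of 0.45 and 0.05, but its members went both ways, 2 of 11 up and 7 down (median -2.58), and miR-51-5p made up most of its reads with GFP::ALG-5. The mir-35 family, which acts in embryos, went from 16.8% of miRNA reads in the input to 58.0% with HA::ALG-2, and from 25.2% to 12.8% with HA::ALG-1, 17.9% to 3.86% with ALG-1::HA::ALG-2 and 18.9% to 11.8% with HA::ALG-5. In the limma test of ALG-5 against the other constructs, the members more enriched were 1 of 14 in the mir-35, 2 of 11 in the mir-51, 1 of 7 in the mir-44 and 2 of 5 in the mir-2 family. Both arms of a hairpin count as members. Those called were miR-36-5p, the minor arm of mir-36, both arms of mir-51, miR-61-3p and both arms of mir-250. limma called 0 members of the let-7, lin-4, mir-58 and mir-64 families and of the mirtrons, where 1, 1, 0, 1 and 0 had an unadjusted p under 0.05. The mir-58 list does not hold miR-58b-3p, which was called.

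**Figure D5:**
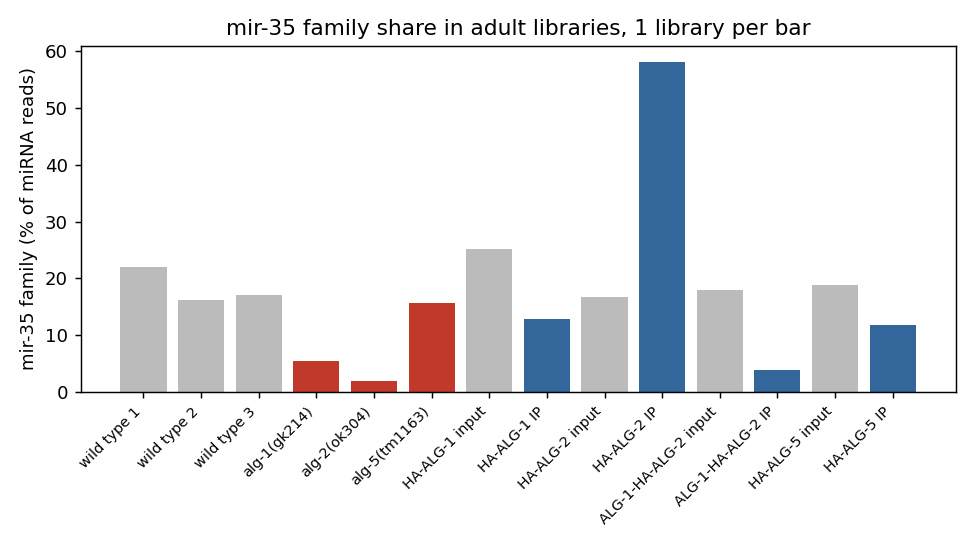
Share of the mir-35 family in the miRNA reads of each adult library, in percent, 1 library per bar (grey, wild type or input; red, mutant; blue, immunoprecipitate). It was 58.0% in the HA::ALG-2 immunoprecipitate, 5.51% in alg-1(gk214) and 1.83% in alg-2(ok304), against 16.114% to 22.0% in wild type adults. The wild type L4 library, not drawn, held 0.794%.

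In adult mutants, 1 library each, miRNAs were set against 3 wild type adults. The mir-35 family made up 1.83% of miRNA reads in alg-2(ok304), 5.51% in alg-1(gk214) and 15.6% in alg-5(tm1163), against 16.114% to 22.0% in wild type. The wild type L4 library held 0.794%, so the share differs with stage. How far the adult mutants had developed was not measured, so stage cannot be told apart from genotype here. miR-36-3p and miR-37-3p had log2 values of -4.11 and -3.93 in alg-2(ok304) (adjusted p = 0.0304 and 0.0436), and miR-35-3p was lower as well (adjusted p = 0.0304). With 1 mutant library, these p take the spread from the wild type adults alone, which come from 3 experiments. Against the wild type library of the same experiment they differed by -3.67, -3.28 and -3.40. These were the 3 of 154 miRNAs that limma called in alg-2(ok304), with 13 at an unadjusted p under 0.05, and adjusted over the list alone 7 of the family passed. Without wild type adult 1 limma called 0, without wild type adult 2 57, and without wild type adult 3 5. limma also called 0 with no filter, scaled to the 4 classes or with the deposited RPM. edgeR called 0 and DESeq2 14, with 12 and 34 at an unadjusted p under 0.05. The adjusted p of miR-36-3p and miR-35-3p reached 0.473 over the alternatives and that of miR-37-3p 0.549. In alg-1(gk214) limma called 0, with 31 at an unadjusted p under 0.05, edgeR 2 (35) and DESeq2 47 (60), and without wild type adult 2 limma called 77, and 2 without wild type adult 3. Its highest value was that of let-7-3p (log2 7.03), the strand opposite mature let-7, followed by miR-2214-5p (5.02), lin-4-3p (4.88), miR-237-3p (4.47) and miR-235-5p (3.81). The lowest were miR-799 (-4.51), miR-78 (-3.99), miR-1822-3p (-2.997), miR-785 (-2.73) and miR-38-3p (-2.45). Against wild type adult 2, of the same experiment, let-7-3p differed by 6.15, lin-4-3p by 3.56 and miR-2214-5p by 1.79. In alg-5(tm1163) limma and edgeR called 0, with 0 at an unadjusted p under 0.05 in each, and DESeq2 1 (5). There let-7-5p differed by 1.68, miR-1-3p by 1.59, miR-791-3p by -2.43, miR-2214-5p by -2.37 and miR-250-3p, which DESeq2 called, by -1.40. limma called none of these. The model has no term for the experiment: against wild type adult 3, of the same experiment, these differed by -0.02, -0.45, -0.53, 0.88 and -1.67. Of 154 miRNAs, 2 were more than 2-fold higher than in that library and 1, miR-250-3p, lower. Without wild type adult 2 let-7-5p differed by 0.41, miR-1-3p by 0.31, miR-791-3p by -1.48 and miR-2214-5p by -0.75. The mutant libraries are assumed to vary as wild type does.

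Small RNA of alg-5(ram2) L4 larvae was set against 1 wild type L4 library, so no test is given. Of the 3 miRNAs that made up most of the GFP::ALG-5 immunoprecipitate, miR-61-3p differed by a log2 of -0.44, miR-250-3p by -2.46 and miR-51-5p by -0.06. Scaled to the miRNA total, with a median log2 of -0.21 over 177 miRNAs, 2 were more than 2-fold higher, miR-790-5p (1.08) and miR-235-3p (1.04), and 25 more than 2-fold lower. The lowest was miR-250-3p, followed by miR-1-3p (-2.23), miR-52-3p (-1.96), miR-1829b (-1.94) and miR-85-5p (-1.89). With the deposited RPM 7 were more than 2-fold higher and 11 lower. The 21U piRNAs made up 1.15% of the 4 classes in alg-5(ram2) and 1.77% in wild type (Wilson 95% intervals 1.15% to 1.16% and 1.77% to 1.78%), and miRNAs 45.5% and 42.3%. Among adults, the miRNA share was 30.4% in alg-2(ok304) (30.4% to 30.5%), above the wild type range of 23.1% to 27.1%. The CSR-1 siRNA share of alg-5(tm1163), 26.6%, lay just above the wild type range of 13.3% to 26.5%, and its Mutator siRNA share, 45.5%, just below a range that starts at 45.8%, by less than the spread between wild type adults.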

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

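The tests of collection hour and of progress toward adulthood, and the interval around the arm ratios, were chosen only after the result was seen. A difference between mutants, or between Argonautes, passed a test of the difference itself in 4 results. In limma 12 genes differed between alg-5(ram2) and alg-5(tm1163), 241 between alg-1(gk214) and alg-2(ok304), and 1404 between alg-1(gk214) and alg-5(tm1163), and 11 miRNAs differed in enrichment between ALG-5 and the ALG-1 and ALG-2 constructs. In the last of these, Argonaute and experiment go together. In both comparisons with alg-1(gk214), collected at 53 h against 49 h, hour and genotype go together.

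The mRNA libraries were also split in other ways, and the splits of 3 against 3, 10 in number, are too few for a share under 0.05. The real split was the 1 with the highest count in each of these comparisons. The real count and the highest of the other splits were 13 and 5 for alg-5(tm1163), 44 and 0 for alg-5(ram2), 2245 and 2 for alg-1(gk214), and 1814 and 1 for alg-2(ok304), each against wild type. They were 12 and 1 between the alg-5 alleles, 241 and 2 between alg-1(gk214) and alg-2(ok304), and 1404 and 1 between alg-1(gk214) and alg-5(tm1163). For both alleles against wild type, with the 6 mutant libraries as 1 group, 3 of 84 splits, the real one among them, gave at least its 5 genes. The others set single alleles against the rest, with the highest count, 19, for alg-5(ram2), which points to a structure of the samples by allele. That model differs from the one behind the 25 genes reported, so it is no test of them.

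Cuticle and molting genes fell in both alg-1(gk214) and alg-2(ok304). The later hour of the alg-1(gk214) animals cannot account for the fall in alg-2(ok304), collected at the hour of wild type, where 28 members fell. In alg-1(gk214) hour and genotype go together, so there the later hour stays open. A few abundant genes that set the scale are argued against, since under median-of-ratios scaling the lower of both counts of members that fell was 28. Animals further along toward adulthood could account for it, as the vitellogenin and adult list had log2 medians above 0 in both mutants, the lower being 1.232. By camera with an estimated correlation that list did not pass (adjusted p = 0.0746 in alg-1(gk214) and 0.211 in alg-2(ok304)). With fry, which asks another question, it passed (adjusted p = 2.64e-05 and 0.000657). The oogenesis list in alg-2(ok304) had 16 members higher and 18 lower (median -0.10), so the explanation stays open beside the genotype itself.

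Major sperm protein genes fell in alg-5(tm1163), alg-1(gk214) and alg-2(ok304). Reads moved between near-identical copies are argued against, since the FPKM summed over the list lay below each wild type library in each library of 3 of 3 mutants. Wild type libraries that are high by chance are argued against as the whole cause for alg-2(ok304), as 0 libraries of alg-5(ram2) or alg-1(gk214) were at or under its highest, and for alg-5(tm1163), as 0 libraries of alg-5(ram2) were; a part of it stays open, since the alg-5(ram2) sums, 2886 to 3607, also lay under the lowest of wild type, 3743. Animals further along toward adulthood cannot be told apart from a direct effect. The oogenesis list and the vitellogenin and adult list passed in 0 of these mutants by camera with an estimated correlation and went different ways. With fry the vitellogenin and adult list passed in alg-1(gk214) and alg-2(ok304). The oogenesis list passed with fry in alg-1(gk214) but not in alg-5(tm1163) (fry adjusted p = 0.000173 and 0.186). The collagen list, which holds adult col-19, passed as higher by camera with an estimated correlation in alg-1(gk214) and alg-2(ok304) (adjusted p = 0.00195 and 0.000188). Of its members 23 and 16 fell, and its median in alg-5(tm1163) was -0.03. The oogenesis list had medians of -0.16 in alg-5(tm1163) (26 of 34 members lower, adjusted p = 0.4545 with an estimated correlation), -0.10 in alg-2(ok304) (adjusted p = 0.8865), where the sperm genes fell most, and 0.46 in alg-1(gk214) (adjusted p = 0.0606), and the vitellogenin and adult list was lower in 8 of 8 members in alg-5(tm1163) (median -0.31, adjusted p = 0.891) and higher in 7 of 8 in each of the others.

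The minor arms of miRNA hairpins were higher against the major arms in adult alg-1(gk214) than in wild type adult 2, by a median log2 of 1.083 over 71 hairpins (95% interval 0.529 to 1.78), with 59 higher and 12 lower. Scaling to the miRNA total cannot move a ratio within a library, so the median of 1.083 is no test of it; the make-up of the library stays open, as the 4 classes held 49.3% of its reads against 65.6% to 76.5% in the other adults without immunoprecipitation. A shift of that experiment's libraries, and low depth that raises minor arms, are argued against by wild type adult 2, the shallowest. It differed from wild type adults 1 and 3 by -0.05839 (-0.602 to 0.278). Low depth could also lower the minor arms of this reference and so widen the shift, and the interval leaves that open. At mir-234, the hairpin with the median shift, the minor arm had 1 read in alg-1(gk214) and 0 in wild type adult 2. alg-2(ok304), of the same experiment, shifted by 0.3717 (0.0956 to 0.844), alg-5(tm1163) by 0.03 and alg-5(ram2) by -0.08. The alg-1(gk214) mutation may raise the minor arms, as a hypothesis from 1 library whose hairpins are not independent.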

How the results depend on the processing

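Library weights, edgeR, the deposited RPM (for L4 alg-5(ram2) too) and the model of the compared groups alone for direct comparisons were chosen only after the result was seen. The counts of the 8 mRNA comparisons stayed within 1.5-fold of those reported under another pseudocount, scaling or a replicate block, and most did under another filter, run only for the 5 comparisons with wild type. With no filter the count for alg-5(tm1163) was 8. A model of the compared groups alone gave 1 for alg-5(tm1163), 16 for alg-5(ram2), 1117 for alg-1(gk214), 1169 for alg-2(ok304), 15 for both alleles, 5 between the alleles, 154 between alg-1(gk214) and alg-2(ok304) and 904 between alg-1(gk214) and alg-5(tm1163), where fewer libraries set the spread. Library weights gave 4 for alg-5(tm1163), 10 for both alleles, 23 between the alleles and 469 between alg-1(gk214) and alg-2(ok304), and the cause was not tested. Leaving out 1 library gave 5 to 32 for alg-5(tm1163), 18 to 73 for alg-5(ram2), 7 to 130 for both alleles, 4 to 8 between the alleles and 107 to 174 between alg-1(gk214) and alg-2(ok304). Lists past the threshold with an estimated correlation were 0 for alg-5(tm1163), 0 for alg-5(ram2), 3 for alg-1(gk214), 4 for alg-2(ok304), 0 for both alleles, 0 between the alleles, 4 between alg-1(gk214) and alg-2(ok304) and 5 between alg-1(gk214) and alg-5(tm1163). With fry, which asks another question, they were 1 for alg-5(tm1163), 0 for alg-5(ram2), 1 for both alleles and 1 between the alleles. DESeq2 and edgeR were not run on the mRNA, since they need counts. Of uncalled genes near 0, these changed sign with 1 library left out: in alg-5(tm1163), alg-2 (-0.17 to 0.0464), hbl-1 (-0.11 to 0.17), lin-28 (-0.078 to 0.41) and lin-41 (-0.44 to 0.035); in alg-5(ram2), hbl-1 (-0.32 to 0.0737), lin-28 (-0.46 to 0.0351) and lin-29 (-0.0646 to 0.0855); in alg-1(gk214), alg-5 (-0.12 to 0.36); in alg-2(ok304), alg-5 (-0.0918 to 0.0675) and lin-28 (-0.48 to 0.0482). With library weights alg-2 in alg-5(tm1163) was 0.00201 and alg-5 in alg-2(ok304) -0.0513. The mean log2 ratio of the miRNA share was 0.726 without Mutator siRNAs, since the total then lacks a large class. The 11 miRNAs more enriched by ALG-5 became 32 with DESeq2, 6 with no filter, 7 without the ALG-1::HA::ALG-2 construct, 5 with edgeR and 21 with the deposited RPM, of which 10 were less enriched, and 7 to 13 with 1 construct left out. In alg-5(ram2) L4 larvae 27 miRNAs differed by more than 2-fold, 25 of them lower, and 18 with the deposited RPM, 11 of them lower. The adult miRNA counts with DESeq2 were 47 in alg-1(gk214), 14 in alg-2(ok304) and 1 in alg-5(tm1163), and with edgeR 2 in alg-1(gk214) and 0 in alg-2(ok304). The count in alg-2(ok304) was 0 with no filter, 0 scaled to the 4 classes and 0 with the deposited RPM. With 1 wild type adult left out it was 0 to 77 in alg-1(gk214) and 0 to 57 in alg-2(ok304). Of 9 piRNA and siRNA shares of adult mutants 2 lay outside the wild type range, and 4 relative to the miRNA total. The depth of wild type adult 2, 1622092 reads, limits the rarest miRNAs.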

Other observations

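The tests of both hypotheses on miRNAs in alg-5 mutants were chosen only after the result was seen. nspb-10, of a family of nematode-specific peptides that no list covers, rose by 5.51 in alg-1(gk214) and 5.53 in alg-2(ok304). Histone genes of the replication-dependent kind were among the genes higher in several mutants, with his-31 up by 3.80 in alg-1(gk214) and 3.45 in alg-2(ok304). Called in all 4 mutants against wild type were 3 genes higher, his-32, trmt-10A and F58A4.6, and 1 lower, F27C1.4, chosen after their values were seen, and all 4 share the wild type libraries. In alg-2(ok304) 7 of 46 histone genes rose, also adjusted over the list alone, and 1 oogenesis gene rose and 2 fell. limma called 0 of 34 germline mitosis and meiosis, 40 siRNA and piRNA machinery and 9 somatic gonad genes in alg-2(ok304), with 0, 7 and 2 at an unadjusted p under 0.05. K05F1.8 was listed at 0 in each alg-2(ok304) library and in some alg-5(tm1163) and alg-1(gk214) libraries, and at 13.5 to 29.6 FPKM in wild type.

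Other families lay outside the wild type range in the adult alg-1(gk214) and alg-2(ok304) libraries, 1 each. The mir-51 family made up 23.7% and 22.7% of miRNA reads, against 6.175% to 16.3% in wild type adults, and the lin-4 family 4.33% and 3.75% against 0.796% to 2.97%. Wild type adult 2, of the same experiment, is the highest of both ranges, and against it the log2 ratios were 0.54 and 0.48 for mir-51 and 0.54 and 0.34 for lin-4. The mir-64 family made up 3.92% and 6.79% against 7.74% to 8.92% (-0.98 in alg-1(gk214) against wild type adult 2), and the mir-58 family 20.4% and 21.9% against 22.4% to 28.0% (-0.14 and -0.03). The mir-44 family made up 0.782% in alg-2(ok304) against 1.03% to 1.64% (-0.40), and the mirtrons 0.0225% in alg-1(gk214) against 0.0245% to 0.0766%. In alg-5(tm1163) the lin-4 family, 0.637%, and the mir-51 family, 5.58%, lay below these ranges, and the mir-58 family, 29.6%, and the mirtrons, 0.0775%, above. Against wild type adult 3, of the same experiment, the log2 ratios were -0.32, -0.15, 0.08 and 0.02. The 4 classes held 49.3% of the reads in alg-1(gk214), 65.6% in alg-2(ok304) and 68.8% to 76.2% in wild type adults.

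The first hypothesis was that alg-5(tm1163) adults hold less of the miRNAs that ALG-5 enriches. Of the 8 measured, 8 were lower than in wild type adult 3, with a median log2 of -0.49 against -0.11 over all miRNAs, at percentile 0.055 of 10000 random lists matched on abundance. The mir-35 family, whose share of miRNA reads was lower in both ALG-5 immunoprecipitates than in their inputs, was lower in 14 of 14 members at percentile 0.08. It holds miR-36-5p, which ALG-5 enriches, so it is not a clean control. The let-7, lin-4, mir-58 and mir-64 families, depleted in both ALG-5 immunoprecipitates, lay at percentiles 82.63, 21.16, 6.015 and 86.74. The test ranks miRNAs within 1 pair of libraries, with no replicate, and the mir-35 family lay about as low. The hypothesis thus stays open. The second was the same for alg-5(ram2) L4 larvae: 6 of 8 were lower, with a median of -0.57, at percentile 25.27. The let-7 and mir-35 families, whose shares were lower in both ALG-5 immunoprecipitates, lay further down there, at percentiles 1.53 and 3.4. In this pair of libraries the ranking does not tell the enriched miRNAs from others, so the hypothesis stays open.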
